A study of Homo sapiens with 6 samples.

How the data were processed

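Sequencing libraries were made from total RNA with a KAPA mRNA HyperPrep kit, per the labels' protocols, from 6 samples of the NCI-H292 cell line: 3 untreated (mock) and 3 co-cultured with Trichomonas tenax. The authors deposited a table of FPKM values, fragments per gene scaled by gene length and library total, for 58884 human genes in these 6 libraries. Trimmomatic, HISAT2, DESeq2 and the genome build GRCh38 are named in the submitters' processing notes, without versions, and the counting tool and gene annotation are not given in the sources used here. Whether parasite reads were removed before mapping is not given either. FPKM divides by each library's total, so a change in a few abundant genes moves every other gene, and dividing by gene length leaves short genes noisy.

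Gene symbols were looked up by Ensembl identifier, with 58472 of 58884 found in a table of gene names and 58611 in GENCODE 29, from which gene types and coordinates on GRCh38 were taken. Some genes carry an older symbol in the deposited table, such as CTGF for CCN2. Each gene's values stood in whole-number ratios once each library was scaled by a constant, within a relative tolerance of 1e-11 and with a common denominator of at most 2000000. This held for 100% of the 20230 genes above 0 in every library, and for 0% of them after relative noise of 1e-06 was added to the values. Genes above 0 in fewer libraries test this less strictly. The gene lengths these ratios imply lay within 1% of the GENCODE 29 union exon length for 77.87% of 10419 well-covered genes. The recovered reads gave the depth of each library, from 16270415 to 21024012 reads, and 3 reads on a gene of 2000 bases corresponded to 0.0714 to 0.0922 FPKM. Such limits cover counting error only.

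Because FPKM is not a count, no count model was the main test. Genes with at least 1 FPKM in at least 3 of the 6 libraries were kept (13196 genes), values were turned into log2(FPKM + 1), and limma 3.58.1 in R 4.3.3 compared co-culture with mock by its moderated test with a trended prior and no replicate block. P-values were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05, and a further count required a difference of at least 1. Fold differences on this scale understate the change of low genes. Of the tested genes, 10992 were protein-coding.

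Before the data were examined, 40 gene lists, the tests, the alternatives and the rule for named genes were fixed. Lists with at least 5 tested members, 38 in all, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and the rotation test fry were alternatives. The rule named the 10 protein-coding genes with the largest rise and the 10 with the largest fall among those past the threshold whose groups did not overlap, then up to 4 members of each list past the threshold by size (or the 2 most abundant where none passed), and the largest rise and fall of lists that moved apart. Further list members named in the text (of the metal, conserved, oxidative phosphorylation, glycolysis, EGFR, p53 and marker lists) were chosen after their values were seen. Some genes that the rule names are not reported here.

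Alternatives were a pseudocount of 0.1, no filter, a minimum of 5 FPKM, median-of-ratios scaling, quantile normalization, no trend, a robust prior, a replicate block, and leaving out each library in turn. Chosen after the data were seen were limma-voom on the recovered reads, protein-coding genes only, and leaving out mitochondrial genes. Replicate libraries differed by more than sampling noise, with a chi-square per degree of freedom from 1.9 to 14, so none was counted as a duplicate.

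The fit was tested on simulated data: reads for the 13196 genes with 200 genes changed. All genes and libraries were given the same dispersion (0.00114), so no simulated library stood apart as co-culture library 3 does in the data. The shares below hold for that setting and were not tested with such a library or with more genes changed. With reads divided by the true depth, it recovered 80% of genes changed 1.5-fold, 92% at 2-fold, 94% at 4-fold and 98% at 8-fold, and 8 of 12996 unchanged genes were called, or 4.21% of calls. When the same reads were divided by each library's own total, as FPKM is, the changed genes moved the totals, unchanged genes shifted by a median of -0.0991 and 605 of them were called, or 76.6% of calls. An unchanged list then reached an adjusted p of 0.0103. Median-of-ratios scaling brought the false calls back to 8. FPKM values can therefore give false calls of small size when abundant genes change. In the deposited values the median difference over all genes was -0.000627, and median-of-ratios scaling gave 5352 changed genes, of which 5076 were also among the 5281 of the unscaled values. Whole-read recovery, given the true simulated library totals, returned 100% of 13196 simulated genes up to a common factor. The estimate of the library constants, and the common factor set from annotated lengths for 1957 genes in the deposited values, were not part of that test. Scripts were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.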

Results

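RNA was sequenced from NCI-H292 cells, a human epithelial line derived from a mucoepidermoid carcinoma of the lung, kept alone or together with Trichomonas tenax, a flagellated protozoan found in the human mouth. The series held 3 libraries of untreated cells, called mock here, and 3 libraries of co-cultured cells. The dose of parasites and the length of the co-culture are not given in the sources used here. Values were FPKM per gene, and whole read numbers recovered from them gave 18894966, 17534217 and 18076661 reads in mock libraries 1 to 3 and 21024012, 18093507 and 16270415 in co-culture libraries 1 to 3. Means below are FPKM with the SD over 3 libraries, and differences are co-culture minus mock on the log2(FPKM + 1) scale with their standard error. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

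The comparison asked how the transcriptome of the epithelial cells differed after co-culture with the parasite. In co-culture, 20 of 21 hypoxia response genes, 21 of 22 glycolysis genes, 30 of 30 mitosis genes and 20 of 23 EGFR ligand and ERK feedback genes were higher. Of 20 cytokines and chemokines, 8 were higher and 5 lower. Of the interferon-stimulated genes, 19 of 27 were lower and none was higher, and of the p53 targets, 14 of 24 were lower and 2 higher. The iron and zinc importers TFRC and SLC39A10 were lower. Of 13196 genes tested, 2806 were higher and 2475 were lower in co-culture (limma, adjusted p under 0.05), and 6498 had an unadjusted p under 0.05. Most of these differences were small: 139 genes rose and 66 fell by at least 1 on the log2 scale, or 205 together, of which 60 were of non-coding or other types and 29 of these had an implied length under 200 bases. The count of 205 became 431 with a pseudocount of 0.1, 466 with limma-voom on recovered reads and 131 with a minimum of 5 FPKM, and the 66 falls became 35 with protein-coding genes alone. The 3 co-culture values lay on the same side of the 3 mock values for 7152 genes, or 54.2% of those tested, where chance gives 10%.

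Among protein-coding genes on the log2(FPKM + 1) scale, which understates the change of low genes, the largest rise was in CA9, a membrane carbonic anhydrase on chromosome 9 (35673856 to 35681159, plus strand, GRCh38), which went from 4.03 ± 0.49 to 44.6 ± 7.9 FPKM, a difference of 3.17 ± 0.14 (adjusted p = 2.25e-05). ENO2, the neuronal form of enolase on chromosome 12 (6913745 to 6923698, plus strand), rose from 1.80 ± 0.12 to 22.5 ± 1.6 FPKM. NDRG1, a stress-responsive gene on chromosome 8 (133237171 to 133302022, minus strand), rose from 13.6 ± 0.7 to 94.6 ± 1.9 FPKM. CYP1A1, a cytochrome P450 induced through the aryl hydrocarbon receptor, rose from 0.192 ± 0.088 to 6.19 ± 0.50 FPKM, on 7 to 17 reads per mock library. Next came ANGPTL4 (difference 2.49), the glucose transporter SLC2A3 (2.47), the secreted glycoprotein STC1 (2.46), the prolyl hydroxylase EGLN3 (2.29), the lysyl oxidase LOX (2.28) and CASP14 (2.21), a caspase of keratinocyte differentiation. On the same scale and among the same genes, the largest fall was in GAS1, on chromosome 9 (86944363 to 86947189, minus strand), from 7.31 ± 0.46 to 1.48 ± 0.34 FPKM, a difference of -1.75 ± 0.11 (adjusted p = 6.81e-05). The transferrin receptor TFRC, on chromosome 3 (196027183 to 196082189, minus strand), fell from 189.9 ± 1.6 to 61.1 ± 6.7 FPKM, a difference of -1.63 ± 0.08 (adjusted p = 2.8e-05). The other large falls were in MXRA5 (difference -1.69), CDH5 (-1.63), the defensin DEFB1 (-1.55), the zinc importer SLC39A10 (-1.49), MAPK4 (-1.32), ODAPH (-1.27), CCN2 (-1.27) and the fatty acid transporter SLC27A2 (-1.26).

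**Figure D1:**
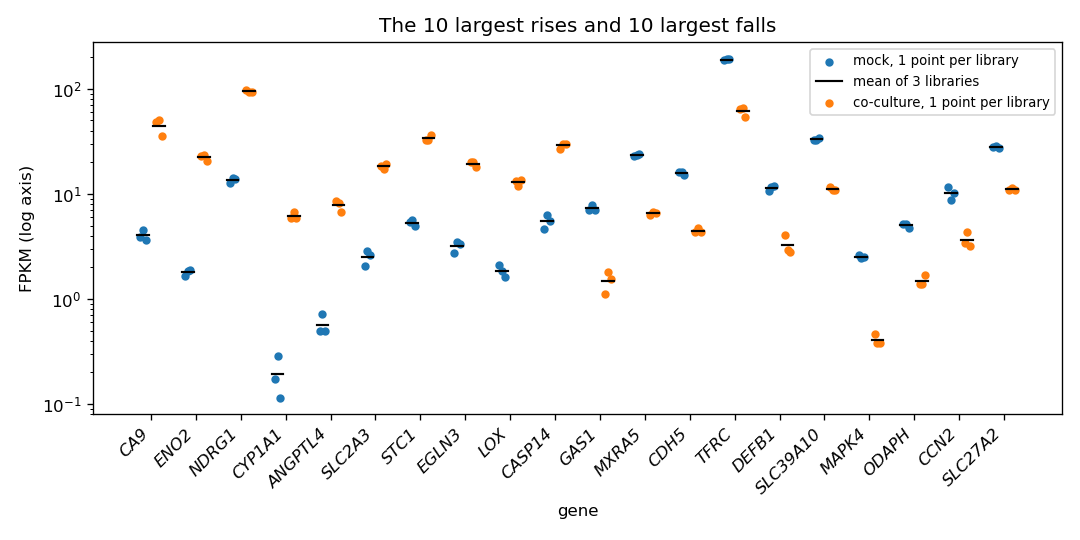
FPKM on a log axis for the 10 genes with the largest rise and the 10 with the largest fall, with blue points for the 3 mock libraries, orange points for the 3 co-culture libraries and a black line at each mean. The co-culture points of each gene lie wholly above or wholly below its mock points, from CA9 (4.03 to 44.6 FPKM) to SLC27A2 (27.9 to 11.02 FPKM).

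Of the 21 hypoxia response genes tested, 20 rose and none fell, with a median difference of 1.12 (camera adjusted p = 1.07e-14). The list call was lost with an estimated correlation (adjusted p = 0.213 with an estimated correlation). After CA9, NDRG1, ANGPTL4 and EGLN3, the members included LOX and the angiogenic growth factor VEGFA (11.4 to 30.4 FPKM), and 12 of the 20 rose by at least 1. Glycolysis genes gave a like count, with 21 of 22 higher and a median of 0.77 (camera adjusted p = 6.97e-13, and adjusted p = 0.287 with an estimated correlation). ENO2, SLC2A3, ALDOC (4.30 to 20.4 FPKM) and the kinase PGK1 (72.4 to 171 FPKM) led this list, and PFKM was the member that did not pass (-0.12, adjusted p = 0.23). The counts adjusted over the list alone were 20 and 21, as over all genes. Nuclear genes of oxidative phosphorylation held 1 rise, in SDHB (0.35), and 2 falls, in NDUFB5 (-0.23) and NDUFA1 (-0.22), among 29 tested, with 1 and 1 adjusted over the list alone (camera adjusted p = 0.302).

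The 13 mitochondrially encoded transcripts held 4 falls and no rise, led by MT-CYB (-0.67), MT-CO3 (-0.45), MT-ND1 (-0.42) and MT-CO2 (-0.39), with 4 adjusted over the list alone. The list passed the preset test (camera adjusted p = 0.0360) and did not pass with an estimated correlation (adjusted p = 0.709 with an estimated correlation) or after quantile normalization (adjusted p = 0.888). It also missed the threshold with median-of-ratios scaling (0.0506), no filter (0.147), a minimum of 5 FPKM (0.0584), fry (0.153) and without mock library 3 (0.0635). Mitochondrial reads made up 11.01 ± 0.28% of the mock libraries and 9.40 ± 1.32% of the co-culture libraries (exact permutation test, two-sided, p = 0.2, with 0.1 the smallest p that 3 against 3 allow). Co-culture library 3 stood apart from the other co-culture libraries, with 10.93% mitochondrial reads against 8.69% and 8.59%, and the adjusted p of the list was 2.53e-07 without it and 0.123 without co-culture library 1 or 2.

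All 30 mitosis genes tested rose, with a median of 0.70, and 30 passed adjusted over the list alone (camera adjusted p = 6.01e-17, and adjusted p = 0.254 with an estimated correlation). HMMR rose from 9.01 to 21.8 FPKM, the ubiquitin-conjugating enzyme UBE2C from 22.8 to 45.2, the checkpoint kinase BUB1 from 7.56 to 15.4 and securin, PTTG1, from 19.6 to 38.0. DNA replication genes rose in 23 of 28 cases, with 23 adjusted over the list alone (camera adjusted p = 6.45e-08, and adjusted p = 0.213 with an estimated correlation). The licensing factor CDT1 (0.95), CDC45 (0.84), cyclin E1, CCNE1 (0.78), and CDC6 (0.65) led it. Of 10 replication-dependent histone genes, 4 fell and none rose, or 5 and none adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.0876). The falls were in H2BC12 (-0.66), H2AC6 (-0.65), H2BC21 (-0.38) and H2BC5 (-0.33), and histone paralogs share sequence, so these values are uncertain. They also rest on few reads, with 114 to 145 per mock library and 69 to 90 per co-culture library for H2BC12. How far the mRNA kit captures histone transcripts was not tested, so these falls do not show how histone transcripts moved as a whole.

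Growth factor signalling genes also differed. In the list of EGFR ligands and ERK feedback genes, 20 of 23 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 2.82e-10, and adjusted p = 0.0694 with an estimated correlation). ERRFI1, a feedback inhibitor of the receptor, rose by 1.91 (1.91 to 9.93 FPKM), the ERK phosphatase DUSP6 by 1.71 and the transcription factor ETV4 by 1.67. The falls were in DUSP10 (-0.51) and BTC (-0.29). Immediate early and AP-1 genes rose in 11 of 21 cases and fell in 3, with 11 and 4 adjusted over the list alone (camera adjusted p = 0.0360, and adjusted p = 0.287 with an estimated correlation). FOS went from 1.81 to 7.95 FPKM, EGR1 from 9.49 to 21.5 and FOSL1 from 2.38 to 5.84, whereas CCN2 fell. That call was also lost without co-culture library 2 (adjusted p = 0.0656) and with a minimum of 5 FPKM (adjusted p = 0.155). YAP and TEAD targets moved apart, with 4 of 17 higher and 7 lower, also adjusted over the list alone (camera adjusted p = 0.223): F3, tissue factor, rose from 227 to 476 FPKM, and CCN2 (-1.27), AJUBA (-0.55) and ARHGEF17 (-0.48) fell.

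**Figure D2:**
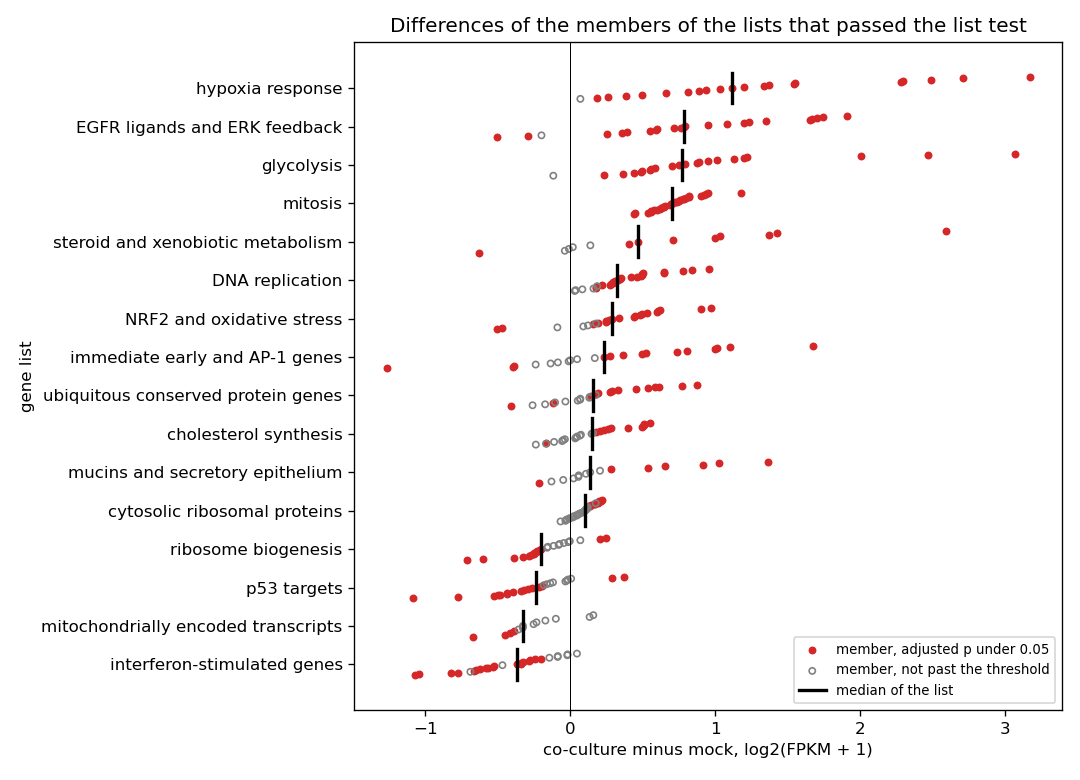
Difference between co-culture and mock on the log2(FPKM + 1) scale for each tested member of the 16 lists that passed the list test with a preset correlation. Filled red points passed the gene threshold, open grey points did not and the black bar is the list's median, which ran from -0.36 for interferon-stimulated genes to 1.12 for the hypoxia response.

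Cytokines and chemokines moved both ways. Of 20 tested, 8 rose and 5 fell, or 10 and 5 adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.0876). Besides VEGFA, the interleukins IL1A (54.4 to 124 FPKM, difference 1.17) and IL1B (8.47 to 20.1 FPKM, 1.16) and the neutrophil chemokine CXCL8 (10.8 to 20.7 FPKM, 0.88) rose, and the largest fall was in CSF1 (-0.54). NF-kB feedback genes and targets held 11 rises and 5 falls among 21, or 12 and 7 adjusted over the list alone, and did not pass as a list (camera adjusted p = 0.124): IER3 (1.25), BIRC3 (0.58), ICAM1 (0.52) and TNIP1 (0.51) rose, and NFKB1 fell by 0.43. Among eicosanoid genes, 6 of 10 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.0548). They included cyclooxygenase 2, PTGS2 (43.5 to 95.2 FPKM), PLA2G4A (0.88), PTGS1 (0.76) and AKR1C3 (0.49), with HPGD lower (-0.32).

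Interferon-stimulated genes fell in 19 of 27 cases and none rose, with 20 lower adjusted over the list alone (camera adjusted p = 6.45e-08, and adjusted p = 0.287 with an estimated correlation). IFI44 went from 5.08 to 1.90 FPKM, HERC6 from 5.89 to 2.35, MX1 from 7.01 to 3.52 and OAS2 from 3.36 to 1.55. Antigen presentation genes showed 3 rises and 3 falls among 17, also adjusted over the list alone (camera adjusted p = 0.938), with ERAP1 (-0.44) and ERAP2 (-0.22) lower and B2M (0.19) higher. Innate sensors and adaptors showed 3 rises and 3 falls among 16, also adjusted over the list alone (camera adjusted p = 0.651), among them TIRAP (-0.42), TLR1 (-0.28), RIPK2 (0.25) and TLR6 (0.22). Inflammasome and pyroptosis genes showed 2 rises among 12, also adjusted over the list alone, in GSDMB (0.59) and CASP4 (0.17), and no fall (camera adjusted p = 0.794).

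Among p53 targets, 14 of 24 fell and 2 rose, with the same counts adjusted over the list alone (camera adjusted p = 5.84e-05, and adjusted p = 0.287 with an estimated correlation). TP53I3 (21.1 to 9.46 FPKM), EDA2R (12.4 to 6.86), AEN (-0.53) and ZMAT3 (-0.50) led the falls, GADD45A rose (0.37), and the cell cycle inhibitor CDKN1A was at 48.8 and 48.5 FPKM (adjusted p = 0.90). Apoptosis regulators held 6 rises and 9 falls among 27, or 6 and 10 adjusted over the list alone (camera adjusted p = 0.315): BIK (0.75), BCL2A1 (0.59) and BIRC5 (0.56) rose and CASP6 fell (-0.50). Heat shock genes held 4 rises and 8 falls among 18, or 4 and 9 adjusted over the list alone (camera adjusted p = 0.0548), with DNAJA1 (-0.77), HSPA1A (-0.75), HSPB8 (-0.75) and HSPA1B (-0.69) lower and FKBP4 higher (0.27). HSPA1A and HSPA1B are near-identical copies, so their separate values are uncertain. The chaperones of the unfolded protein response held 3 rises and 5 falls among 20, also adjusted over the list alone (camera adjusted p = 0.938), with XBP1 (-0.30), HSPA5 (-0.27) and HERPUD1 (-0.23) lower and HSP90B1 higher (0.22). ATF4 and amino acid stress genes held 8 rises and 5 falls among 27, or 9 and 5 adjusted over the list alone (camera adjusted p = 0.397), led by STC2 (1.29), the cystine transporter SLC7A11 (0.97) and VLDLR (0.84), with ATF5 lower (-0.78). Autophagy and lysosome genes held 5 rises and 6 falls among 26, also adjusted over the list alone (camera adjusted p = 0.978), with SQSTM1 (-0.47), BECN1 (-0.34) and CTSL (-0.33) lower and NPC1 (0.37) higher.

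Oxidative stress genes controlled by NRF2 rose in 17 of 23 cases and fell in 2, or 18 and 2 adjusted over the list alone (camera adjusted p = 3.68e-05, and adjusted p = 0.287 with an estimated correlation). SLC7A11 went from 8.90 to 18.4 FPKM and the thioredoxin reductase TXNRD1 from 24.4 to 46.4, ABCC3 (0.62) and GSR (0.60) rose, and AKR1C1, which has close paralogs, fell (-0.51). Steroid and xenobiotic metabolism genes rose in 8 of 13 cases and fell in 1, with the same counts adjusted over the list alone (camera adjusted p = 7.06e-04, and adjusted p = 0.300 with an estimated correlation). Besides CYP1A1, CYP1B1 went from 2.56 to 8.54 FPKM, ALDH1A3 from 23.4 to 62.0 and ALDH3A1 from 7.35 to 16.1, whereas NNMT fell by 0.63.

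Metal genes moved apart. Of 14 metallothionein and metal transport genes, 7 rose and 6 fell, with the same counts adjusted over the list alone, so the list as a whole showed no direction (camera adjusted p = 0.918). Transport proteins made up the falls: TFRC and SLC39A10, the iron exporter SLC40A1 (10.5 to 6.499 FPKM), the zinc exporter SLC30A1 (16.9 to 11.3 FPKM), SLC39A8 (-0.38) and SLC11A2 (-0.31). The rises were in the metallothioneins MT1X (5.72 to 16.1 FPKM), MT2A (136 to 299 FPKM), MT1F (0.60) and MT1E (0.52), the siderophore-binding LCN2 (522 to 926 FPKM) and the ferritin chains FTL (0.60) and FTH1 (0.48). Metallothionein genes are near-identical copies, and reads can be shared between them.

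**Figure D3:**
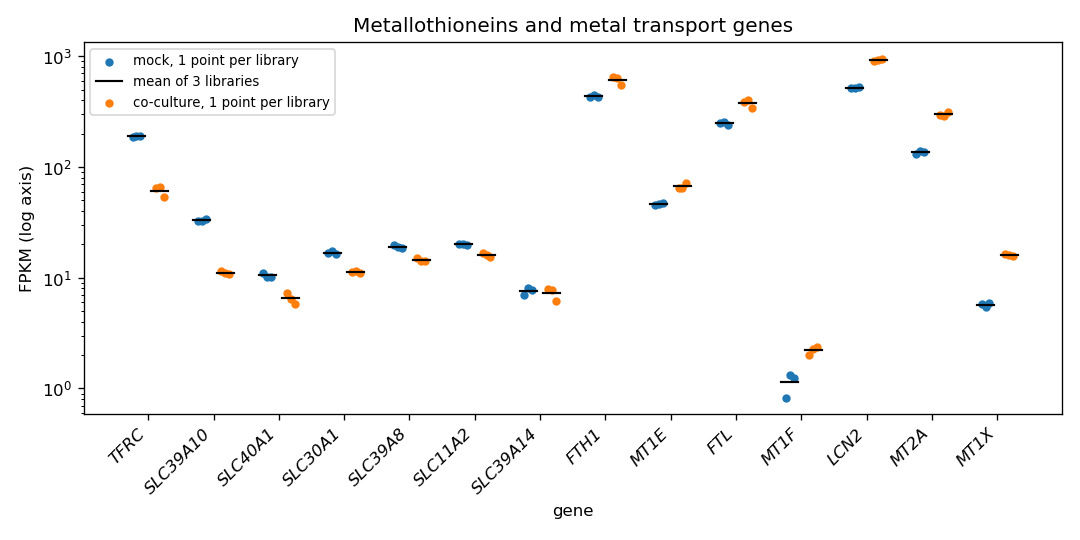
FPKM on a log axis for the 14 tested metallothionein and metal transport genes, ordered by their difference, with blue points for the 3 mock libraries, orange points for the 3 co-culture libraries and a black line at each mean. TFRC (189.9 to 61.1 FPKM) and SLC39A10 (33.1 to 11.1 FPKM) stand at the left and MT2A (136 to 299 FPKM) and MT1X (5.72 to 16.1 FPKM) at the right.

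Mucin and secretory genes rose in 6 of 15 cases and fell in 1, with the same counts adjusted over the list alone (camera adjusted p = 0.0412, and adjusted p = 0.287 with an estimated correlation). MUC5AC, a gel-forming airway mucin, went from 0.911 to 3.95 FPKM, TFF1 from 2.30 to 5.74, MUC2 from 0.378 to 1.62 and AGR2 from 20.5 to 32.9, and ST6GAL1 fell (-0.22). The TFF1 values rest on 9 to 13 reads per mock library and 24 to 28 per co-culture library. The mucin call was lost without mock library 3 (adjusted p = 0.0517) or co-culture library 2 (adjusted p = 0.0535), with a minimum of 5 FPKM (adjusted p = 0.133) and without the trend (adjusted p = 0.0504). Antimicrobial and protease inhibitor genes held 9 rises and 3 falls among 18, or 9 and 4 adjusted over the list alone (camera adjusted p = 0.150): LCN2, S100A9 (384 to 668 FPKM) and PI3 (0.66) rose and DEFB1 fell. Junction and desmosome genes held 10 rises and 5 falls among 28, or 13 and 5 adjusted over the list alone (camera adjusted p = 0.129), with CLDN4 (0.62), CDH3 (0.52), PKP2 (0.51) and NECTIN2 (0.46) higher and CTNNB1 lower (-0.38). Integrin and hemidesmosome genes held 10 rises and 5 falls among 22, or 10 and 6 adjusted over the list alone (camera adjusted p = 0.111). ITGA5, the fibronectin receptor subunit, went from 3.89 to 15.2 FPKM, the laminin chains LAMA3 (0.67) and LAMB3 (0.52) rose, and DST fell (-0.32).

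Mesenchymal genes held 3 rises and 4 falls among 12, or 3 and 6 adjusted over the list alone (camera adjusted p = 0.379), with ITGA5 higher and CDH2 (-0.83) and TAGLN (-0.73) lower. Matrix proteases and inhibitors held 8 rises and 4 falls among 19, or 9 and 5 adjusted over the list alone (camera adjusted p = 0.315). The collagenase MMP1 (1.09) and PLAT (0.89) rose and MMP13 fell (-0.94). Actin cytoskeleton and SRF target genes held 5 rises and 4 falls among 22, also adjusted over the list alone (camera adjusted p = 0.938): MYL9 (-0.83) and TPM1 (-0.69) fell and CNN3 (0.54) rose. The median and the mean of this list differed in sign (0.01 and -0.03), as did those of antigen presentation (0.02 and -0.0044), unfolded protein response (0.01 and -0.0036) and autophagy genes (0.03 and -0.0021), and fry gave the mesenchymal list an upward and the antigen presentation list a downward direction, neither past the threshold.

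Cholesterol synthesis genes rose in 11 of 25 cases and fell in 1, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.0180, and adjusted p = 0.570 with an estimated correlation). FDFT1 (0.51), HMGCS1 (0.51) and INSIG1 (0.51) were among the rises and IDI1 fell (-0.16). Fatty acid synthesis genes held 6 rises and 2 falls among 16, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.223), with TMEM97 (0.42), ELOVL6 (0.33) and ACSL3 (0.32) higher and SREBF1 lower (-0.36). Cytosolic ribosomal protein genes rose in 10 of 34 cases, 9 adjusted over the list alone, and none fell (camera adjusted p = 0.00816, and adjusted p = 0.594 with an estimated correlation). RPS2 (0.22), RPL32 (0.22) and RPL11 (0.20) were among these small rises. After quantile normalization the call was lost (adjusted p = 0.322), as with fry (adjusted p = 0.0964), and RPS2 stood at -0.0051. The adjusted p of the list was 2.9e-08 without co-culture library 3, and 0.0326 and 0.0499 without co-culture libraries 1 and 2. Ribosome biogenesis genes fell in 13 of 24 cases and rose in 2, or 14 and 2 adjusted over the list alone (camera adjusted p = 0.00146, and adjusted p = 0.287 with an estimated correlation). RRS1 (-0.71), UTP20 (-0.60), POLR1A (-0.38) and POLR1B (-0.32) fell and NPM1 rose (0.25), and the call was lost with a minimum of 5 FPKM (adjusted p = 0.0529).

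A list of ubiquitous genes whose proteins are conserved across eukaryotes rose in 12 of 24 cases and fell in 2, or 12 and 3 adjusted over the list alone (camera adjusted p = 0.00620, and adjusted p = 0.486 with an estimated correlation). ENO1 (0.87), the tubulins TUBA1B (0.77) and TUBB (0.61) and GAPDH (0.58) led the rises and HSPA8 fell (-0.41). The elongation factor EEF1A1 was at 2161 and 2242 FPKM (adjusted p = 0.44) and ACTB at 946 and 880 FPKM (adjusted p = 0.12). Whether parasite reads were removed before mapping is not given in the sources used here, so the values of conserved genes can include such reads. Of 16 macrophage and leukocyte markers, CD14 alone passed the filter on low values (4.84 and 4.34 FPKM, adjusted p = 0.41), and the pan-leukocyte gene PTPRC had means of 0.014 and 0.0114 FPKM. Of 14 fibroblast and endothelial markers, CDH5 and COL1A1 were tested and both fell, by 1.63 and by 0.32, also adjusted over the list alone. Untested members went both ways at low values, with mock and co-culture means of 0.615 and 1.11 FPKM for PECAM1 and 0.115 and 0.0712 for VWF. Neither of these marker lists had the 5 tested members a list test needed.

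Library-wide correlations of log2(FPKM + 1) between replicates ran from 0.9894 to 0.9904, apart from the pairs with co-culture library 3 at 0.9843 and 0.9841, and ran from 0.9618 to 0.9678 between groups. None of the 16 list calls made with the preset correlation of 0.01 held with an estimated correlation between genes. For the EGFR and mucin lists the estimates were below the preset value (-0.0015 and -0.0627), so a higher correlation was not what ended those calls. Something else in that setting raised the adjusted p, from 2.82e-10 to 0.0694 for the EGFR list, and its nature was not tested. The estimates were also low for immediate early (0.0252), ribosome biogenesis (0.0335) and DNA replication genes (0.062), and reached 0.977 for mitochondrial transcripts. Losing a call in that setting is therefore not by itself evidence of correlated genes. Nor is it a weakness particular to a list, since none of the 38 lists tested passed there. Without co-culture library 3, 5824 genes passed, against 5281 with it.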

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

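The tests with limma-voom on recovered reads, protein-coding genes only and mitochondrial genes left out were chosen after the data were seen. Alternatives that need deposited counts (edgeR, DESeq2) were not run, since the table holds FPKM. The count of changed genes ran from 3584 (minimum of 5 FPKM, fewer genes tested) to 5835 (limma-voom) around 5281, and 47.6% to 56.5% of calls were higher. Genes called both there and in the reported fit had the same direction in each alternative, which a call in both fits of largely the same libraries makes near certain. Of the 5281 calls, those kept ran from 3432 (minimum of 5 FPKM) to 5250 (robust prior). Without a filter 3808 were kept, and 3846 without mock library 1. The labels' replicate numbers gave no pairing: deviations of same-numbered libraries correlated at -0.034, 0.034 and -0.00092, and of the 6 samples the pair numbered 2 alone correlated best with its own number, and the replicate block gave 4508 changed genes. Of 169 named genes in 2839 combinations with a setting, 2767 kept direction and call, 70 in 20 genes lost the call, and 2 reversed: RPS2 after quantile normalization (-0.0051) and CD14, not called, without co-culture library 3 (0.0069, with -0.226 at the other end of the left-out libraries). Of these genes, 168 were past the threshold in the reported fit, and most were named for the size of their change. Their share of kept calls therefore does not stand for all called genes.

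Counts of genes changed by at least 1 moved with a pseudocount of 0.1 (431, with 279 higher and 152 lower), with limma-voom (466, with 302 higher and 164 lower) and with a minimum of 5 FPKM (131, with 37 lower), and protein-coding genes alone gave 35 lower. A smaller pseudocount lets low genes reach larger differences by construction. With an estimated correlation none of the 38 lists passed: adjusted p was 0.0694 for EGFR ligands, 0.213 for hypoxia and DNA replication, 0.254 for mitosis, 0.287 for glycolysis, interferon, p53, NRF2, immediate early, ribosome biogenesis and mucin genes, 0.300 for steroid metabolism, 0.486 for conserved genes, 0.570 for cholesterol, 0.594 for ribosomal proteins and 0.709 for mitochondrial transcripts. Fry, which does not compare a list with other genes, called 25 lists, newly cytokines (3.61e-05), NF-kB (7.74e-04), heat shock (7.65e-04), fatty acids (0.0270), histones (0.00511), junctions (0.00236), antimicrobial genes (0.00877), proteases (0.00182), integrins (7.65e-04), YAP targets (0.0179) and eicosanoids (3.22e-04), and lost mitochondrial transcripts (0.153) and ribosomal proteins (0.0964). Without regard to direction, fry passed all 38 lists, so its calls say little about how a list stands among other genes.

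Without a filter, cytokines (0.0148), NF-kB (0.0304), heat shock (0.0174), histones (0.00796), junctions (0.0109) and integrins (0.0304) passed and mitochondrial transcripts did not (0.147). A minimum of 5 FPKM ended the calls of immediate early (0.155), mitochondrial (0.0584), ribosome biogenesis (0.0529) and mucin genes (0.133). Median-of-ratios scaling ended the mitochondrial call (0.0506), quantile normalization the mitochondrial (0.888) and ribosomal protein calls (0.322), and no trend the mucin call (0.0504). Heat shock genes passed after quantile normalization (0.0264), with limma-voom (0.0324) and with protein-coding genes (0.0479). The cause was not tested. Leaving out 1 library at a time gave adjusted p from 0.0198 to 0.0656 for immediate early genes, 0.0448 to 0.0656 for heat shock, 2.53e-07 (without co-culture library 3) to 0.123 for mitochondrial transcripts, 0.0437 to 0.153 for histones, 0.0326 to 0.0535 for mucins and 0.0437 to 0.1 for eicosanoids. Depth of 16270415 to 21024012 reads left low genes such as CYP1A1 on 7 to 17 reads in the mock libraries.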

Other observations

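Of the tests below, those on TFRC, on conserved genes, on the mitosis list, on SLC30A1 and on mock RNA in co-culture library 3 were chosen only after the result was seen.

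Outside the fixed lists and the 20 genes of largest change, 60 protein-coding genes rose and 22 fell by at least 1 on the log2 scale, and the genes named here were chosen after their values were seen. PPFIA4 rose from 0.177 to 4.42 FPKM, HILPDA, a lipid droplet protein, from 3.37 to 15.9, the lysyl oxidase relative LOXL2 from 4.55 to 21.9 and ERO1A, an oxidase of the endoplasmic reticulum, from 20.5 to 69.1. The peptidylarginine deiminases PADI1 (0.340 to 2.86 FPKM) and PADI3 (0.592 to 3.31 FPKM) rose, as did the keratin KRT6A (0.649 to 2.70 FPKM), SCEL (17.4 to 37.3 FPKM) and the stress ligand ULBP2 (7.57 to 17.9 FPKM). The clock genes NR1D1 (1.94 to 6.78 FPKM) and PER1 (1.95 to 5.24 FPKM) were higher. The Wnt inhibitor DKK1 fell from 72.5 to 30.8 FPKM, the transcriptional inhibitor ID3 from 76.1 to 31.7, the glutamate transporter SLC1A3 from 112.8 to 49.8 and the RNA-binding ZFP36L2 from 60.8 to 25.3. A further 60 genes of non-coding or other types changed by at least 1, of which 29 had an implied length under 200 bases, where FPKM is noisy.

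Of the 10 splits of the 6 libraries into 3 and 3, 1, the real split, gave as many changed genes, with 5281 against 0 in the highest other split, and 10 splits are too few for a share under 0.05.

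Of the hypoxia and glycolysis lists, 20 of 21 and 21 of 22 tested genes rose, and both list calls were lost with an estimated correlation (adjusted p = 0.213 and adjusted p = 0.287 with an estimated correlation). Removing a smooth trend on GC content and length left the median of their 41 tested members at 0.892 (0.597 to 1.13, 95% bootstrap interval), against 0.887 before, which argues against that trend as the cause. The bootstrap intervals here and below draw genes, not libraries, so they do not measure the spread between samples. Conserved genes, taken as those that parasite reads assigned to human genes would reach first, had a median of 0.14 (0.0603 to 0.233) without their glycolysis members, far below both lists. They include abundant genes such as EEF1A1, with 205956 to 226241 reads per mock library. Added reads move the log2 difference of such genes less than that of low genes such as CA9, with 105 to 129. The conserved list also holds a low gene, TUBA1A, with 145 to 154 reads per mock library. It had 155 to 201 per co-culture library, where CA9 had 930 to 1635. TUBA1A is a single gene, and the median of 0.14 rests largely on more abundant ones. That median therefore does not decide whether parasite reads had a part in these lists. Their share in the conserved genes themselves was not tested. Iron withdrawal by the parasite would raise TFRC, which fell by 1.63 (-1.78 to -1.47, a range from its standard error and not a bootstrap interval). Lower oxygen in the co-culture is a candidate explanation that stays open, since no measure of oxygen was analysed here, as does a change of medium or density that went with the co-culture.

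TFRC and SLC39A10 fell while metallothioneins and ferritins rose. Fewer dividing cells would lower the mitosis list, whose median was 0.703 (0.64 to 0.769). Zinc loading would raise the exporter SLC30A1, which stood at -0.539 (-0.613 to -0.464 from its standard error). SLC30A1 was the only gene in that test. The metallothioneins, which rose, were not part of it, so zinc loading is left undecided. Iron loading remains possible: CDC14A, with an iron-responsive element in its transcript, stood at -0.0922 (-0.248 to 0.0633 from its standard error, adjusted p = 0.386), which does not decide. That test used CDC14A alone. The metal transporters SLC11A2 and SLC40A1, which fell past the threshold, were not part of it. A regulated fall of TFRC with the hypoxia response was not tested.

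Co-culture library 3 lay apart from co-culture libraries 1 and 2 on the component that took 14.6% of the variance (18.6 against -9.69 and -10.4). Mock RNA as the whole cause would keep library 3 between the mock mean and the other co-culture libraries, yet 87.2% of 257 deviating genes lay outside that range. A smaller admixture cannot be told apart from regression to the mean: the slope of library 3's differences on those of libraries 1 and 2 was 0.922 (0.907 to 0.938), and library 1 and library 2 gave 0.923 and 0.913 in the same test. Lower depth is argued against, since over 3379 genes of at least 1000 reads the SD of library 3 from the others was 0.141, against 0.0815 and 0.0819. A trend on GC content and length took up 28.4% of that variance, so a difference in library preparation may account for part of it, and what made up the rest stays open.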
